A study of Mus musculus with 18 samples.

How the data were processed

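RNA from epidermal sheets of mouse back skin was measured on Affymetrix gene arrays, with total RNA turned into biotin-labelled cDNA, per the labels' protocols. The labels describe 18 samples, 3 for each of 6 groups formed by genotype (AhR-/- and AhR+/+ littermates) and time after tape stripping (0, 6 and 24 h), and the groups and replicate numbers were taken from the sample titles. The titles name separate samples and the series text speaks of littermates per time point, so each array was treated as 1 animal. The labels also give a 4-digit number per sample whose meaning is not given in the sources used here; it was split at 3000 as a possible batch. The p-values set a difference between groups against the spread between samples of the same group, and the number of arrays limits their precision.

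The authors deposited 1 table of 33793 rows (transcript clusters) by 18 arrays, with 0 columns of other samples. Its values are taken as log2 per the deposited numbers themselves: they run from -6.4 to 4.3, and the median of 100% of the rows over the 18 arrays is 0 within 1e-06, so the authors had centred each row. A base of 10 would imply impossible ranges, but a natural log is not ruled out, in which case every difference would be larger on the log2 scale by the same factor. The background correction, summarisation, normalisation between arrays and software are not given in the sources used here. Array medians ran from -0.0187 to 0.0107 and SDs over all rows from 0.134 to 0.222. Because the row level was removed, signal over background could not be assessed, no filter on dim rows by mean signal was possible, and dim rows stay in every count.

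Rows were named through the platform's probe table: 23521 had 1 gene symbol, 1814 several and 8458 none. The 23521 rows, which name 22180 genes (1082 of them by more than 1 row), were tested and no gene was named from the others. The gene table of assembly GRCm38.p6 was used only for names, gene spans and which genes neighbour Ahr within 20 Mb, and none of its coordinates are given.

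Tests used limma 3.58.1 in R 4.3.3 on the values as deposited. A single model with a mean for each of the 6 groups was fitted over all 18 arrays, so that the groups share 1 estimate of the spread (12 residual and 2.76 prior degrees of freedom). Moderated 2-sided tests were made for 9 planned contrasts: KO against WT at each time, 6 h and 24 h against 0 h within each genotype, and the difference between genotypes in each of these responses. P-values were adjusted by Benjamini-Hochberg over all 23521 rows of a contrast, and a row passed at an adjusted p under 0.05. With 3 arrays against 3, an exact permutation test of 1 gene cannot give a 2-sided p below 0.1, so none is reported. A further contrast, KO against WT averaged over the 3 times, was added after the data were seen.

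The 29 gene lists were drawn up from general knowledge, with 792 members of which 710 were measured, and 28 were tested. They cover AhR targets, cornified envelope and late differentiation, epidermal lipid synthesis, cholesterol synthesis, tight junctions and desmosomes, epidermal proteases and inhibitors, wound keratins and alarmins, cytokines and chemokines, immediate early genes, wound repair (EGFR ligands, proteases and matrix), cell cycle, NRF2 targets, interferon response, circadian clock, unfolded protein and heat shock response, and hypoxia and glycolysis. Cell type lists cover basal keratinocytes, hair follicle, sebaceous gland, Langerhans cells, epidermal T cells, neutrophils and monocytes, melanocytes, dermal fibroblasts, endothelium, skeletal muscle, adipocytes and mast cells; of blood haemoglobins 1 of 8 was measured, so that list was not tested. Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the residuals, and with fry, and p-values were adjusted over the 28 lists. Every list called by camera lost its call with an estimated correlation, in all 9 comparisons and in the added contrast. The plan took the row of highest mean for a gene with several rows; after centring a mean says nothing, so the row with the largest SD over the 18 arrays was used.

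The genes named follow a rule: Ahr; the 12 largest changes in each direction among genes that passed, skipping predicted and unnamed models and small RNAs; the 3 smallest p in each direction where none passed; up to 4 members per list with the smallest p; sex-linked genes; and genes within 20 Mb of Ahr. Which of the list members to name among those was decided after their values were seen.

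The 9 comparisons, the lists, the naming rule, the number class and a set of other ways to run the tests were fixed before the data were examined. These other ways were a second quantile normalisation, a shift of each array to 1 median, all rows in place of named rows, limma's trend and robust options, array weights, fits on the groups of a comparison alone, the replicate number as a block, the number class as a block, a fold minimum of 1.5, and leaving out each array in turn. On centred values quantile normalisation makes the spread of deviations the same in every array. Added after the data were seen were fits without the WT arrays of lower numbers at 0 h, at 6 h or at both, a filter on the SD of a row in place of the planned filter on mean signal, which was not run, and removal of a trend with gene span. Shared replicate numbers were not taken to pair the arrays, as described with the alternatives.

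The procedure was tested on simulated data over 23521 rows with 200 changed rows in each of 5 runs. For KO against WT at 6 h it recovered 70.4% of rows changed 1.5-fold, 97.3% at 2-fold and 99.7% at 3-fold, with 5.11% false calls. For the difference between genotypes in the 6 h response it recovered 51.3%, 85.1% and 97.9%, with 6.25% false calls. For KO against WT at 6 h a shifted list of 30 genes was found in 5 of 5 runs by camera and by fry, with 0 false lists. The simulated genes varied independently of one another, whereas the estimated correlation within the measured lists reached 0.374 (T cell markers). These runs therefore do not show how often camera at its preset correlation calls a false list in the real data. They also held no shift tied to the number class and no array out of order. Their rates of recovery and of false calls for rows therefore need not hold in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.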

Results

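The aryl hydrocarbon receptor (AhR) is a ligand-activated transcription factor that is active in keratinocytes, the main cells of the epidermis. Whole-gene arrays were read for epidermal sheets of female mice, either of the AhR-null line B6.129-AhRtm1Bra/J (AhR-/-, here KO) or their littermates that carry AhR (AhR+/+, here WT). Shaved back skin was left unstressed (0 h) or was stressed by tape stripping, in which adhesive film pulls off the outermost cornified layers, and was taken 6 h or 24 h later. Each of the 6 groups of genotype and time held 3 arrays, 18 in all. The deposited values are on a log scale, taken here as base 2 since a natural log could not be ruled out from the values, and each row's median over the 18 arrays had been removed. They carry differences between arrays and no absolute level. Array medians lay between -0.02 and 0.01 log2, and the spread of the values within an array had SDs of 0.134 to 0.222 log2. Of 33793 rows, the 23521 that name a single gene were tested. The number of arrays per group limits the precision of every value below.

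The deleted gene was looked at first. Ahr lay lower in every KO array than in every WT array of the same time. Its centred value was -0.03 ± 0.08 (SD, n = 3) in KO and 0.29 ± 0.30 (SD, n = 3) in WT at 0 h, -0.68 ± 0.08 and 0.43 ± 0.32 at 6 h, and -0.66 ± 0.08 and 0.04 ± 0.07 at 24 h. The KO minus WT difference was -1.11 (SE 0.143) log2 at 6 h, which passed limma's moderated test (adjusted p = 0.00549). The differences of -0.32 at 0 h (adjusted p = 0.556) and -0.70 at 24 h (adjusted p = 0.22) did not. The null allele removes part of the gene, and the array's row for Ahr may read parts outside the deletion, so this check of the labels is partial. The Y-linked genes Eif2s3y, Kdm5d and Uty stayed between -0.06 and 0.12 in all 18 arrays, so no array stood apart from the rest in these genes. Xist ranged from -1.03 to 1.54.

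**Figure D1:**
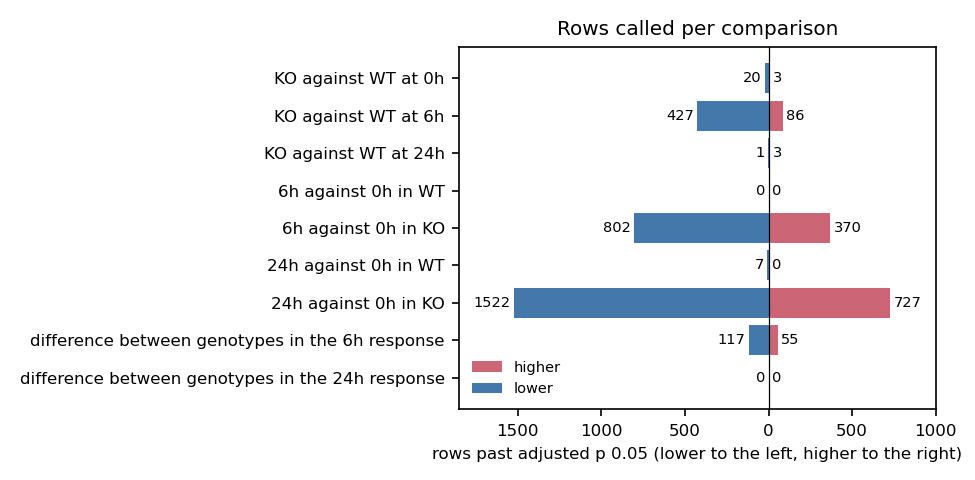
Rows past an adjusted p of 0.05 in each of the 9 planned comparisons, with lower rows to the left of 0 and higher rows to the right (x axis, number of rows). The KO time comparisons reach 1172 rows at 6 h and 2249 at 24 h, against 0 and 7 in WT.

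The comparison of KO with WT at 0 h asks how loss of AhR changes unstressed epidermis. Transcripts of T cells were lower in KO. Trgv5, a variable segment of the gamma chain carried by the gamma-delta T cells that live in mouse epidermis, fell by 3.11 log2 (SE 0.294, 3 arrays per group, adjusted p = 0.000431), an 8.62-fold difference. Cd3e, a chain of the T cell receptor complex, fell by 1.61 (adjusted p = 0.0145) and Il2rb, a chain of interleukin receptors on T and NK cells, by 0.79. Outside the fixed T cell list, Trat1, an adaptor of the T cell receptor, fell by 1.40, Rgs1 by 1.29, the lectin receptor gene Klrb1b by 1.25 and Prf1 (perforin) by 0.89. Mfge8, which bridges dying cells to phagocytes, fell by 2.01 (SE 0.21, adjusted p = 0.000606), and Ptgs2, the inducible cyclooxygenase, by 2.04 (SE 0.333, adjusted p = 0.0372). Tnfaip2, Smox and Dpep2 fell by 1.02, 0.90 and 0.89, and the differentiation keratin Krt1 fell by 0.67 (adjusted p = 0.0212). Higher in KO were Cd59a, an inhibitor of complement, by 1.07 (SE 0.127, adjusted p = 0.00241), the muscle-atrophy ubiquitin ligase gene Fbxo32 by 0.94 and Lypd6b by 0.37.

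In all, 23 rows passed at 0 h, 3 higher and 20 lower, and 1994 had an unadjusted p under 0.05. In each of the 23, the KO and WT arrays did not overlap, which held for 13.7% of all rows and is given by chance for 10%. The 23 rows were chosen for a large difference against their spread in these arrays. Their lack of overlap follows largely from that choice and adds no support. Of the 18 measured epidermal T cell markers, 3 passed (9 when adjusted over the list alone), all lower. The list was lower by camera (adjusted p = 2.65e-13), with an adjusted p = 0.261 when its correlation was estimated. Camera also placed Langerhans cell markers lower (median -0.23; 1 of 19 passed, 3 adjusted over the list alone, adjusted p = 1.35e-06), with Cd207 at -0.70 (adjusted p = 0.287). The p with an estimated correlation was 0.313. The lists of cornified envelope, wound repair matrix and proteases, cell cycle, and sebaceous gland genes had camera adjusted p of 0.0254, 0.00222, 0.0254 and 0.00412, each with an adjusted p = 0.699 with an estimated correlation. Their medians were -0.08, -0.10, -0.05 and -0.19, and 1 (Krt1), 1 (Ptgs2), 0 and 0 members passed (1, 1, 3 and 1 adjusted over the list alone). The T cell marker Cd7 differed by -1.67 (adjusted p = 0.0659). Among 12 measured AhR target genes, none passed, Cyp1a1 differed by -0.31 (adjusted p = 0.527) and Aldh3a1 by -0.53 (adjusted p = 0.286), and camera gave the list an adjusted p = 0.0666. Fry, a rotation test of whether a list's genes move 1 way, called 2 lists at 0 h, AhR targets (median -0.17, 4 of 12 above 0) and T cell markers, both lower with an adjusted p = 0.0132.

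The labels give each sample a 4-digit number of unstated meaning, which was below 3000 for 1 KO and 2 WT arrays at 0 h (replicates 2 and 3 of WT) and from 3000 up for the others. Within the lower numbers Trgv5 differed by -2.45, Cd3e by -1.50, Mfge8 by -1.77 and Ptgs2 by -1.77. Within the higher numbers they differed by -3.28, -1.44, -2.02 and -2.44. Krt6a turned direction between the classes, at -2.84 within the lower numbers and 0.289 within the higher ones. Each class leaves 1 array in a group of 0 h, so these values are effect sizes only. They do not show that any of these differences passes within a class. Here and below, a group left with 1 array in a number class is assumed to vary like the other groups of that class. With the number as a block, which takes 1 shift for all times and cannot remove a shift particular to 0 h, 20 rows passed. The count was 5 without KO replicate 2, 5 without KO replicate 3, 59 without WT replicate 1, 7 without WT replicate 2 and 6 without WT replicate 3, and 0 without both of these last arrays or when only the 6 arrays of 0 h were fitted. Of 16 passing genes examined under every alternative, Cd59a, Mfge8, Rgs1, Trat1 and Trgv5 passed whichever single array was left out, and all 16 kept their sign.

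**Figure D2:**
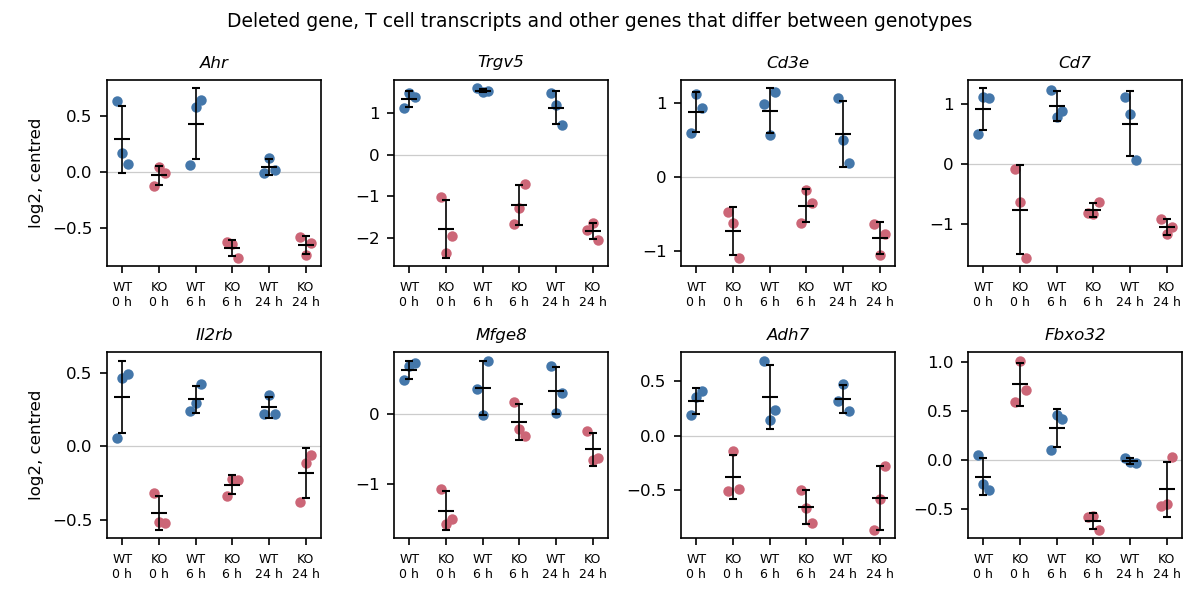
Centred log2 value (y axis) of the deleted gene Ahr and of 7 genes that differ between genotypes, per array (points) with the group mean and SD (bars), WT in blue and KO in red, at 0, 6 and 24 h. Trgv5 lies between -2.38 and -0.71 in all 9 KO arrays and between 0.71 and 1.59 in all 9 WT arrays.

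At 6 h after tape stripping, T cell transcripts were again among those lower in KO. The T cell transcripts Trgv5, Cd7, Cd3e and Il2rb fell by 2.76 (SE 0.294, adjusted p = 0.00312), 1.73 (adjusted p = 0.0167), 1.28 and 0.58 log2 in KO, 3 arrays per group. Several immediate early genes, transcription factors and RNA-decay genes switched on within minutes of a stimulus, were lower in KO, among them Egr1 by 0.63 (SE 0.132, adjusted p = 0.0289), Zfp36 by 0.58, Junb by 0.49 and Egr2 by 0.46. Some genes of cell contacts fell too, with the claudin Cldn8 lower by 0.74, Tjp3 by 0.57, and the cornified envelope linkers Evpl by 0.50 and Ppl by 0.46. Higher in KO were the wound keratin Krt6b by 3.21 (SE 0.794, adjusted p = 0.0499), the glutathione transferase Gsta4 by 2.66 (SE 0.527, adjusted p = 0.0231), the inflammatory cytokine Il1b by 1.80 (SE 0.402, adjusted p = 0.0346), Rab31 by 1.76, Gsdmc by 1.72 and the antimicrobial peptide gene Defb3 by 1.04.

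At 6 h, 513 rows passed, 86 higher and 427 lower in KO, and 3713 had an unadjusted p under 0.05. The KO and WT arrays did not overlap in 508 of them, which follows largely from their choice, and in 17.7% of all rows. Of 29 measured immediate early genes, 8 passed, all lower (17 adjusted over the list alone), with a camera adjusted p = 4.29e-11 and an adjusted p = 0.162 with an estimated correlation. Tight junction and desmosome genes were lower in 5 of 33 (9 adjusted over the list alone; camera adjusted p = 1.84e-05), with an adjusted p = 0.162 with an estimated correlation. Of 32 genes of epidermal lipid synthesis, 2 were lower (9 adjusted over the list alone), the ceramide-producing enzyme gene Smpd1 by 0.53 and the ceramidase gene Acer1 by 0.51; camera gave an adjusted p = 4.68e-05 and the estimated correlation an adjusted p = 0.439. Of 26 wound keratins and alarmins, Krt6b and Defb3 were higher (7 adjusted over the list alone; camera adjusted p = 6.73e-05, adjusted p = 0.439 with an estimated correlation), while Krt6a differed by 2.64 (adjusted p = 0.08). The T cell list had 4 lower members of 18 (8 lower and 1 higher adjusted over the list alone), a camera adjusted p = 4.68e-05 and an adjusted p = 0.45 with an estimated correlation.

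Several other genes of the epidermis passed at 6 h without a call for their list. Of 56 late differentiation genes 5 fell (7 adjusted over the list alone), among them Flg2 by 0.86, Calml3 by 0.53, Dmkn by 0.25 and Sbsn by 0.25. That list had a median of -0.04, a mean of 0.01 and a camera adjusted p = 0.382 in the lower direction. The progenitor markers Lgr6 and Krt15 fell by 0.83 and 0.61, the laminin gene Lamb3 by 0.68, the protease gene Klk5 by 0.58 and Dgat2, an enzyme of triglyceride synthesis, by 0.59. Adh7, a retinol-oxidising dehydrogenase, fell by 1.01, Fbxo32 by 0.95, Rspo3 by 1.05, Neurl1b by 1.12, Mt4 by 1.06, Serpina12 by 0.94, and Ovol1 and Flrt1 by 0.94 each. Slfn2, Gadl1, Ddr2, Stom, Epb41l3 and Nop56 were higher by 1.31, 1.29, 1.14, 1.004, 0.91 and 0.89. The replication licensing gene Mcm6 rose by 0.50 and Sod2 by 0.42, while Ephx1 fell by 0.55. Mcm6 was the 1 of 45 cell cycle genes that passed, while that list had a median of -0.17 with 12 members above 0 (camera adjusted p = 0.32). The AhR targets Nqo1 and Cyp1b1 differed by -0.53 (adjusted p = 0.0671) and -0.59 (adjusted p = 0.072). Over the 12 measured AhR targets the median was -0.12 with 3 above 0, and 0 passed (2 lower adjusted over the list alone). Fry called this list lower (adjusted p = 0.00707), along with the immediate early and junction lists (adjusted p = 0.00602 for both), while camera did not call the AhR targets (adjusted p = 0.204, and 0.439 with an estimated correlation).

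Numbers below 3000 were carried by replicates 2 and 3 of both genotypes at 6 h. Within these 4 arrays 1660 rows passed, 424 higher and 1236 lower, with Trgv5 at -2.51, Il1b at 1.79, Junb at -0.61 and Egr1 at -0.78. The pair of higher numbers gave 0 rows, with Trgv5 at -3.26, Il1b at 1.82, Junb at -0.25 and Egr1 at -0.32. The count was 1034 without KO replicate 1, 182 without KO replicate 2, 24 without KO replicate 3, 1068 without WT replicate 1, 46 without WT replicate 2 and 16 without WT replicate 3. It was 1 without both WT replicates 2 and 3, and 0 when only the 6 arrays of 6 h were fitted. Of 47 passing genes examined under every alternative, Ahr and Trgv5 passed whichever single array was left out, Krt6b passed under 3 of 18 alternatives, and all 47 kept their sign.

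At 24 h, 4 rows passed between KO and WT. Trgv5 was again lower in KO, by 2.97 log2 (SE 0.294, 3 arrays per group, adjusted p = 0.00122). Csta3, a cystatin-family protease inhibitor with near-identical copies whose probes may be shared, rose by 2.38 (SE 0.351), Clec2l by 0.69 (SE 0.101) and Slc25a10, a mitochondrial dicarboxylate carrier, by 0.64 (SE 0.0902), each with an adjusted p = 0.0393. Wound genes had large differences that did not pass, with Krt6b at 3.12 (adjusted p = 0.434), Il1b at 2.04 (adjusted p = 0.197), Lcn2 at 1.66 (adjusted p = 0.391), Krt16 at 1.66 (adjusted p = 0.543) and S100a9 at 0.69 (adjusted p = 0.198). Among other T cell markers Cd3g differed by -1.75 (adjusted p = 0.133), Cd7 by -1.72 (adjusted p = 0.122) and Cd3e by -1.40 (adjusted p = 0.0709).

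Of the 4 rows at 24 h, 3 were higher and 1 was lower, and 1579 rows had an unadjusted p under 0.05. Camera placed 9 lists apart, none of which kept its call with an estimated correlation, where the smallest adjusted p was 0.266. Wound keratins and alarmins lay higher (median 0.22; camera adjusted p = 4.29e-07; 0 of 26 passed, 8 adjusted over the list alone), with an adjusted p = 0.301 with an estimated correlation. The T cell list lay lower (median -0.21; camera adjusted p = 3.68e-08; 1 of 18 passed, 6 adjusted over the list alone), with an adjusted p = 0.301 with an estimated correlation. Cell cycle, interferon response, cytokine, and neutrophil and monocyte genes lay higher, with medians of 0.12, 0.11, 0.04 and 0.06 and camera adjusted p of 1.14e-05, 0.000541, 0.00703 and 0.0247. With an estimated correlation their adjusted p were 0.482, 0.266, 0.419 and 0.419, and 0 members of each passed (2, 1, 1 and 0 adjusted over the list alone). Hair follicle, lipid synthesis, and junction and desmosome genes lay lower, with medians of -0.17, -0.12 and -0.08 and camera adjusted p of 1.14e-05, 0.00421 and 0.0152. Their adjusted p with an estimated correlation were 0.419, 0.528 and 0.419, and 0 members of each passed (0 adjusted over the list alone). The hair follicle result rested largely on WT replicate 2, with a list mean of 0.586. WT replicates 1 and 3 had 0.104 and 0.0502, and the KO arrays 0.0903, 0.0281 and 0.0155. All 6 arrays of 24 h carry numbers from 3000 up. Trgv5 passed under every alternative, while 1 row passed without KO replicate 1 or 3, or without WT replicate 1, 2 or 3.

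**Figure D3:**
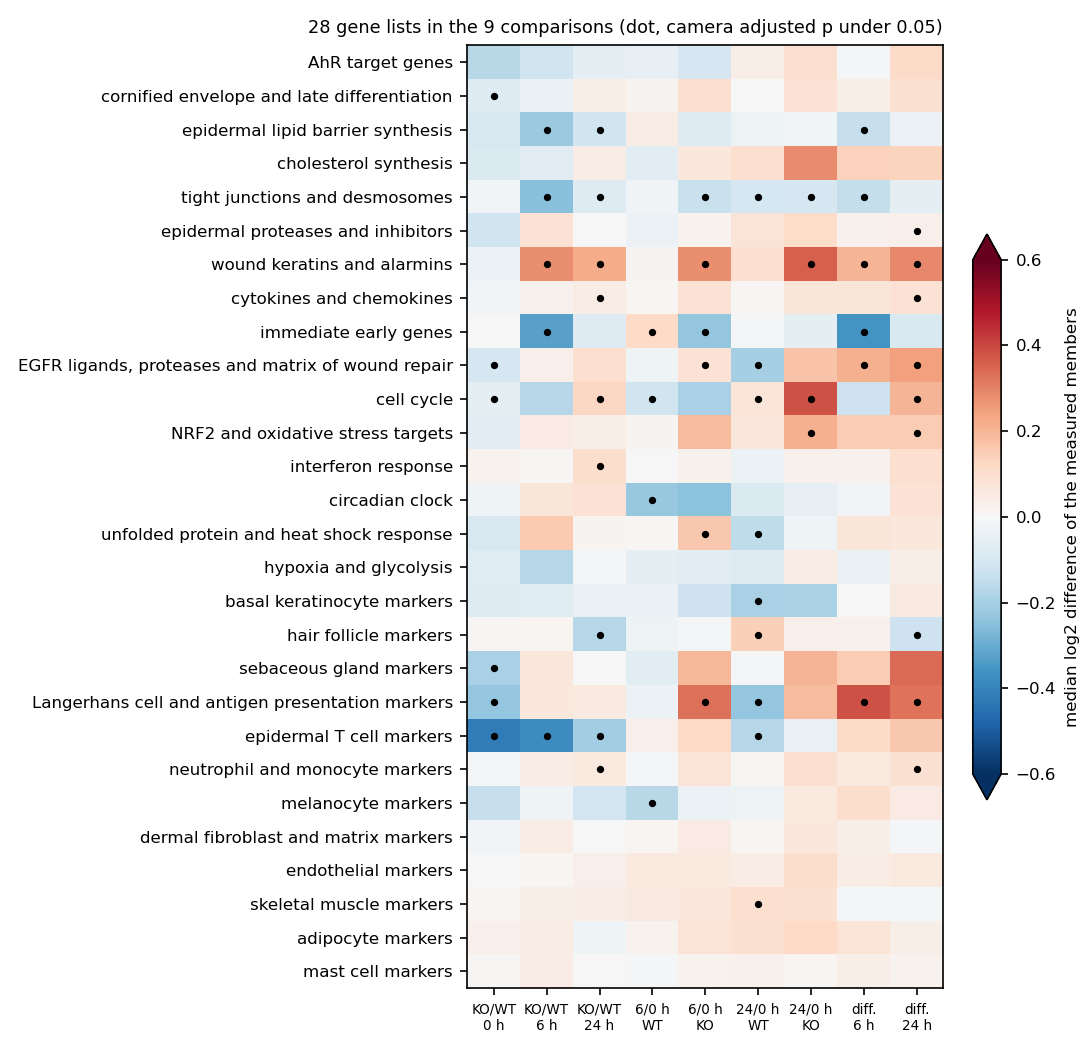
Median log2 difference of the measured members (colour) of 28 gene lists (rows) in the 9 planned comparisons (columns), with a dot where camera at a preset correlation gave an adjusted p under 0.05. T cell markers have medians of -0.42, -0.38 and -0.21 in KO against WT at 0, 6 and 24 h; no dot remains when the correlation is estimated.

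The comparison of 6 h with 0 h in WT asks how normal epidermis answers tape stripping early on. No gene passed in limma (0 rows; 1086 had an unadjusted p under 0.05; smallest adjusted p 0.229). The smallest p in each direction belonged to Pramel24 (0.35, adjusted p = 0.229), Hs3st6 (0.67, adjusted p = 0.952) and Bcl2l1 (0.29, adjusted p = 0.952), and to Clspn (-0.50, adjusted p = 0.883), Pde3b (-0.37, adjusted p = 0.883) and Mcm6 (-0.55, adjusted p = 0.952). By camera, immediate early genes lay higher (median 0.12, adjusted p = 0.000334), with Jund at 0.57 and Egr1 at 0.32 (adjusted p = 1 for both). Melanocyte, circadian clock and cell cycle genes lay lower, with medians of -0.17, -0.23 and -0.12 and camera adjusted p of 4.23e-05, 0.000767 and 9.35e-06. Examples were Tyrp1 at -0.93, Pmel at -0.59, Cry2 at -0.50, Hlf at -0.34 and Mcm2 at -0.58, none of which passed, and the clock gene Npas2 at 0.83. The fall in the cell cycle list came from replicate 1, with list means of 0.226 at 0 h and -0.285 at 6 h. Replicates 2 and 3 had -0.202 and 0.0665 at 0 h and -0.03 and -0.0157 at 6 h. Clock list means were 0.135 and -0.263 in replicate 1. In replicates 2 and 3 they were 0.157 and 0.0501 at 0 h and 0.0955 and -0.0923 at 6 h. Melanocyte list means in replicates 1, 2 and 3 were 0.486, 0.0417 and 0.148 at 0 h. At 6 h they were -0.0747, -0.113 and -0.00513, so a large part of that fall came from replicate 1 at 0 h.

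With an estimated correlation, the adjusted p in WT at 6 h were 0.512 for immediate early, 0.47 for melanocyte, 0.47 for clock and 0.543 for cell cycle genes. No list member passed over all genes; adjusted over the list alone, 0, 1, 0 and 6 were lower. Fry gave adjusted p of 0.556, 0.4, 0.4 and 0.733. WT replicates 2 and 3 at both times carry numbers below 3000. Within them 1 row passed and the keratin Krt6a differed by -2.76, whereas between the 2 arrays of higher numbers, 1 at each time and so with no spread of their own, 6 rows passed and Krt6a differed by 2.03. Leaving out any single array gave 0 rows, and leaving out the 4 arrays of lower numbers, so that each time had 1 WT array assumed to vary like the other groups, gave 44. Without those 4 arrays the immediate early list turned its direction (camera adjusted p = 0.213).

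In KO, 3 wound keratins were among the genes with the largest rise at 6 h. Krt6b, Krt16 and Krt6a, keratins made by epidermis after injury, rose by 3.73 (SE 0.794, adjusted p = 0.0183), 3.08 (SE 0.477, adjusted p = 0.00805) and 3.02 log2 (SE 0.74, adjusted p = 0.0319), 3 arrays per group. Gsta4 rose by 3.01 (adjusted p = 0.0112), the protease inhibitor genes Stfa1 and Stfa3 by 2.94 and 1.58, the envelope precursor Sprr1b by 2.48, Rab31 by 2.07, Klk6 by 1.68, the peptide hormone precursor Guca2a by 1.59, the water channel Aqp3 by 1.54 and Il1b by 1.54 (SE 0.402, adjusted p = 0.0406). Fbxo32 fell by 1.39 (SE 0.142, adjusted p = 0.00168), Rspo3 by 1.39, Slitrk6 by 1.33, Klhl24 by 1.23 and Arrdc3 by 1.28. Ddx5, Dleu2, Il31ra, Irf1, Aspn, Itih5 and Skint7 fell by 1.49, 1.32, 1.30, 1.29, 1.26, 1.23 and 1.22. Krt6a and Krt6b, like the stefin genes and the Skint family, are close copies of one another, and their probes may be shared.

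In KO at 6 h, 1172 rows passed, 370 higher and 802 lower. Of 26 wound keratins and alarmins 6 rose, Defb3 by 0.96 among them (11 adjusted over the list alone; camera adjusted p = 0.000206). Of 33 wound repair genes 5 rose, with Mmp3 at 1.42, Ptgs2 at 1.35 and Itgb1 at 0.47 (10 adjusted over the list alone; camera adjusted p = 0.0104). Of 23 unfolded protein response genes 5 rose, with Sdf2l1 at 1.03, Creld2 at 1.01, Asns at 0.99 and Manf at 0.55 (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0469). Langerhans cell markers lay higher (2 of 19 rose, Mfge8 by 1.26 and Ctss by 0.81; 2 adjusted over the list alone; camera adjusted p = 0.00396). Of 29 immediate early genes 5 fell and 1 rose, with Fos at -0.69, Egr1 at -0.59, Zfp36 at -0.57 and Junb at -0.47 (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000252). Of 33 junction and desmosome genes 5 fell, with Cldn8 at -0.70, Dsc1 at -0.64, Ppl at -0.49 and Marveld2 at -0.42 (6 adjusted over the list alone; camera adjusted p = 0.000696). Each of these 6 lists had, with an estimated correlation, an adjusted p = 0.534. The wound repair list had a mean of 0.416 in KO replicate 1 at 6 h, against -0.0502 and 0.0181 in replicates 2 and 3. In KO at 0 h its means were -0.109, -0.151 and -0.0988, so a large part of the rise rested on 1 array. In lists that camera did not call, Flg2 fell by 1.06, Lipm by 0.90 and Acer1 by 0.71. Of 56 cornified envelope genes, Flg2 among them, 3 fell and 1 rose (4 and 3 adjusted over the list alone), with a median of 0.10 and a camera adjusted p = 0.267 in the higher direction. Of 32 lipid synthesis genes, Lipm and Acer1 were the 2 that fell (2 adjusted over the list alone; camera adjusted p = 0.109). Cyp1b1, an AhR target, fell by 0.74, the chemokine Cxcl10 by 0.85, and Mcm2 rose by 0.55. Mcm2 was the 1 of 45 cell cycle genes that passed, while that list had a median of -0.20 with 12 members above 0 (camera adjusted p = 0.0555). The list of epidermal proteases and inhibitors was not called (3 of 28 rose and 1 fell, 4 and 1 adjusted over the list alone; camera adjusted p = 0.245, fry adjusted p = 0.284).

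Within the numbers below 3000 (2 KO arrays at 6 h, 1 at 0 h) 1 row passed in KO at 6 h, with Krt6a at 3.06 and Krt16 at 2.28, and within the higher numbers (1 KO array at 6 h, 2 at 0 h) 975 passed, with Krt6a at 3.68 and Krt16 at 4.06. The count was 159 without 0 h replicate 2, 252 without 0 h replicate 3, 619 without 6 h replicate 2, 528 without 6 h replicate 3 and 661 when only the 6 arrays were fitted. Of 49 passing genes examined, 12 passed under every alternative: Acer1, Aqp3, Creld2, Fbxo32, Gsta4, Klhl24, Krt16, Lipm, Mfge8, Rab31, Rspo3 and Slitrk6.

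At 24 h in WT, 7 genes passed, all lower than at 0 h. Nol8, a nucleolar protein, fell by 1.09 log2 (SE 0.143, 3 arrays per group, adjusted p = 0.0418), Trat1 by 1.04 (SE 0.146, adjusted p = 0.0472) and the endoplasmic reticulum chaperone Hsp90b1 by 0.81 (SE 0.126). The splicing-associated gene Pnn, the Golgi protein Gcc2, the helicase Dhx9 and the peptidase Erap1 fell by 0.71, 0.63, 0.58 and 0.55, and for these 4 and Hsp90b1 the adjusted p rounds to 0.05. Wound keratins did not pass, with Krt6b at 1.62 (SE 0.794, adjusted p = 0.427), nor did the T cell and leukocyte marker Ptprc at -0.97 (adjusted p = 0.0636) or the mitotic kinase Cdk1 at 0.62 (adjusted p = 0.0826).

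By camera 9 lists stood apart in WT at 24 h, and none kept its call with an estimated correlation (smallest adjusted p = 0.517). Hair follicle genes (median 0.14, adjusted p = 0.000359; Krt31 at 0.73, adjusted p = 0.219), skeletal muscle markers (0.10, adjusted p = 0.0372) and cell cycle genes (0.08, adjusted p = 0.0372; Ube2c at 0.87, adjusted p = 0.0981) lay higher. Their adjusted p with an estimated correlation were 0.517, 0.517 and 0.775. The hair follicle list mean was 0.586 in replicate 2 at 24 h, against 0.104 and 0.0502 in replicates 1 and 3. At 0 h it ran from -0.0487 to 0.111, so the rise rested largely on 1 array. Lower lay Langerhans cell markers (-0.23, adjusted p = 0.00486), wound repair genes (-0.20, adjusted p = 0.00557), basal keratinocyte markers (-0.19, adjusted p = 0.00541) and T cell markers (-0.17, adjusted p = 0.0372), with adjusted p of 0.604, 0.604, 0.517 and 0.644 with an estimated correlation. Unfolded protein response genes (-0.15, adjusted p = 0.0372) and junction and desmosome genes (-0.10, adjusted p = 0.00541) lay lower too, both with an adjusted p = 0.517 with an estimated correlation. Hsp90b1 was the single list member past the threshold over all genes; adjusted over the list alone, 7 cell cycle genes, 1 wound repair gene and 0 of the others were higher, and 2 wound repair, 2 unfolded protein response, 1 basal and 1 T cell gene were lower.

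For WT at 24 h, 2946 rows had an unadjusted p under 0.05, and 0 rows passed when any of the 6 arrays (WT replicates 1, 2 and 3 at 0 h and at 24 h) was left out or with the replicate number as a block. Quantile normalisation gave 264 rows, 71 higher and 193 lower, and array weights 164. Within numbers from 3000 up, which leaves 1 WT array at 0 h that is assumed to vary like the other groups, 390 passed, 111 higher and 279 lower, and without the 4 WT arrays of lower numbers 423 passed, including all 7; there the T cell and cell cycle lists turned direction (camera adjusted p = 0.954 and 0.293).

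In KO at 24 h the wound keratins were again among the genes with the largest rise. Krt6b rose by 5.33 log2 (SE 0.794, 3 arrays per group, adjusted p = 0.00204), a 40.4-fold difference, Gsta4 by 3.91 (SE 0.527, adjusted p = 0.0015), Krt6a by 3.72 (SE 0.74, adjusted p = 0.00698), Krt16 by 3.40 (SE 0.477, adjusted p = 0.00165) and Sprr1b by 3.38. The protease inhibitors Stfa1, Stfa3 and Csta3 rose by 3.60, 2.85 and 2.73, the kallikrein proteases Klk6 and Klk13 by 2.28 and 1.42, the natriuretic peptide gene Nppb by 2.22, the late envelope gene Lce3d by 2.14 and Igfl3 by 2.12. Cell division genes rose, with the kinase Plk1 up by 1.16, Mcm2 by 1.07, Mcm3 by 0.97 and Cdk1 by 0.97. Lower were Skint10, Skint7 and Skint4, members of a family of epidermal proteins, down by 1.42, 1.29 and 1.29, and Klhl24, Calcrl, Slitrk6 and Sema3d, down by 1.46, 1.37, 1.31 and 1.29. Aspn, Ddx5, Zfp960, Zfp617 and Zfp280d fell by 1.43, 1.38, 1.51, 1.30 and 1.26.

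In KO at 24 h, 2249 rows passed, 727 higher and 1522 lower. Of 45 cell cycle genes 18 rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 8.35e-08). Of 26 wound keratins and alarmins 7 rose, S100a9 by 0.84 among them, and 1 fell (13 and 2 adjusted over the list alone; camera adjusted p = 4.7e-05). Of 28 oxidative stress targets of NRF2 7 rose and 1 fell, with Pgd at 0.51, Gsr at 0.43 and Gclm at 0.32 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00179). Of 33 junction and desmosome genes 7 fell, with Dsg1a at -0.67, Dsc3 at -0.60 and Dsc1 at -0.57 (9 adjusted over the list alone; camera adjusted p = 0.0126). Each of these 4 lists had, with an estimated correlation, an adjusted p = 0.525. Camera did not call the other lists. Fry called these 4 and 5 others, all higher: proteases and inhibitors, endothelial, skeletal muscle and adipocyte markers (adjusted p = 0.0341 for each) and neutrophil and monocyte markers (adjusted p = 0.0387). In lists called by neither test, Ptgs2 rose by 1.60, Fabp5 by 1.49, Elovl3 by 1.46, the chemokine Cxcl1 by 1.13, Sprr2h by 0.93, the AhR target Aldh3a1 by 0.80 and Cidea by 0.77. Flg2, Cxcl14, Itga2 and Hsp90b1 fell by 0.88, 0.85, 0.76 and 0.74.

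Ahr itself fell by 0.65 (adjusted p = 0.0209) and 0.62 log2 (adjusted p = 0.0147) from 0 h to 6 h and 24 h in KO, and differed by 0.14 (adjusted p = 1) and -0.25 (adjusted p = 0.524) in WT, which did not pass. This depends on the WT arrays of lower numbers: within the higher numbers, with 1 WT array at 0 h, Ahr in WT differed by -0.57 at 6 h (adjusted p = 0.0943) and fell by 0.59 at 24 h (adjusted p = 0.0343), against -0.64 and -0.67 in KO. Within the lower numbers it differed by 0.49 in WT at 6 h (adjusted p = 0.292) and by -0.58 in KO. The KO count at 24 h was 1206 without 0 h replicate 2, 1029 without 0 h replicate 3, 1219 without 24 h replicate 1 and 1484 without 24 h replicate 3. Within the arrays of numbers from 3000 up it was 2533, and of 48 passing genes examined 36 passed under every alternative, Krt6b, Krt6a, Krt16, Gsta4, Mcm2, Cdk1 and Plk1 among them.

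**Figure D4:**
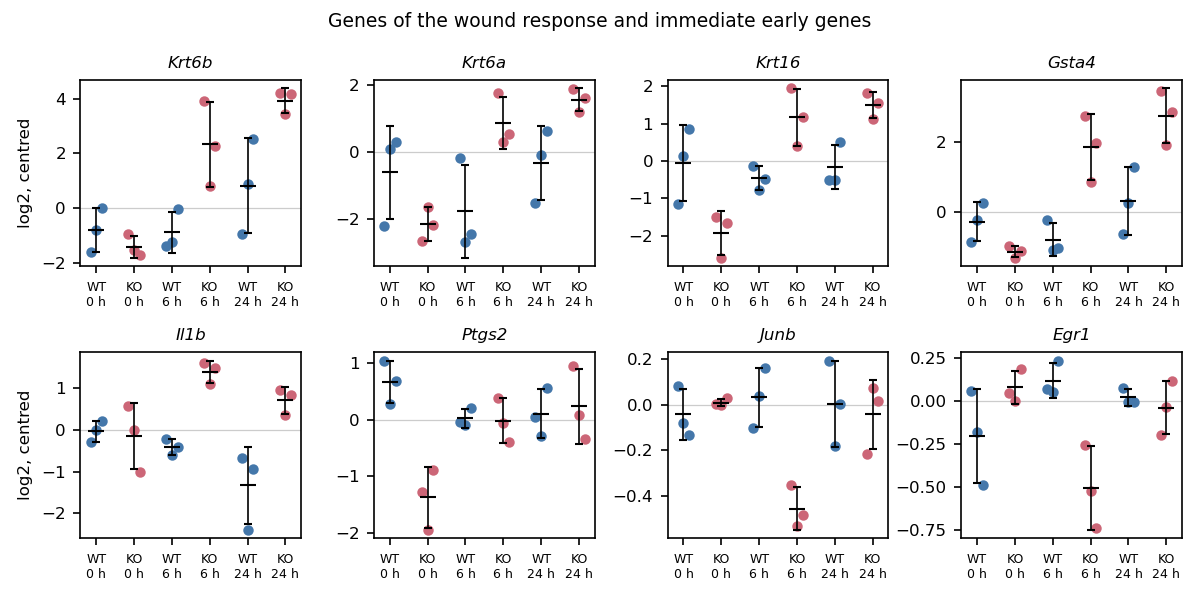
Centred log2 value (y axis) of 8 genes of the wound and early stress response per array (points) with the group mean and SD (bars), WT in blue and KO in red, at 0, 6 and 24 h. Krt6b averages -1.40 at 0 h and 3.94 at 24 h in KO, and -0.80 and 0.82 in WT, where the 3 arrays of 24 h run from -0.94 to 2.53.

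Whether the response itself differed between genotypes was tested as the change in KO minus the change in WT. At 6 h Gsta4 had a difference of 3.52 log2 (SE 0.746, adjusted p = 0.047) and Krt16 of 3.50 (SE 0.674, adjusted p = 0.0391). The replication licensing genes Mcm5, Mcm2, Mcm3 and Mcm6 differed by 1.30, 1.13, 1.07 and 0.76, each higher in the KO response. They were the 4 of 45 cell cycle genes that passed (7 adjusted over the list alone), while the list had a median of -0.12, a mean of -0.01, 13 members above 0 and a camera adjusted p = 0.854 in the higher direction. Lower in the KO response were Fbxo32 by -1.89 (SE 0.2, adjusted p = 0.00288), Rspo3 by -1.83, the BMP and WNT regulator Sostdc1 by -1.51, Slitrk6 by -1.46, Cldn8 by -1.06, Egr1 by -0.91 and Il22ra1, a receptor chain for an interleukin of T cells, by -1.23 (SE 0.143, adjusted p = 0.00465). Krt6a and Krt6b had differences of 4.19 (adjusted p = 0.0793) and 3.81 (adjusted p = 0.127), which did not pass.

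In the 6 h response 172 rows differed, 55 higher and 117 lower in KO, and 3080 had an unadjusted p under 0.05. Rab31, Gadl1, Nrg1, Capn2, Aqp3, Ddr2, Mfge8, Crispld2 and Utp4 were higher by 2.28, 2.08, 1.90, 1.78, 1.71, 1.65, 1.53, 1.38 and 1.29. Fam180a, Hs3st6, Slc6a4, Rasgrp1, Kcnj2, Klhl24 and Mrgprb3 were lower, at -1.41, -1.37, -1.32, -1.31, -1.28, -1.26 and -1.25, as were Calml3, Acer1 and Dgat2 at -0.73, -0.72 and -0.70. Calml3 was the 1 of 56 cornified envelope genes that passed and Dgat2 the 1 of 19 sebaceous gland genes, and camera called neither list (medians 0.04 and 0.15, adjusted p of 0.635 and 0.36). By camera the immediate early (median -0.36, adjusted p = 5.35e-07; 1 of 29 passed, 11 adjusted over the list alone), junction (-0.14, adjusted p = 0.0194; 1 of 33 passed, 4) and lipid synthesis lists (-0.14, adjusted p = 0.0471; 1 of 32 passed, 3) lay lower. Wound keratins (0.20, adjusted p = 0.00103; 1 of 26 passed, 5 adjusted over the list alone), Langerhans cell markers (0.38, adjusted p = 0.00103; 1 of 19 passed, 1) and wound repair genes (0.21, adjusted p = 0.0153; 0 of 33 passed, 5) lay higher. With an estimated correlation the adjusted p were 0.782 for lipid synthesis and 0.703 for each of the other 5. In the wound repair list KO replicate 1 at 6 h stood apart, with a list mean of 0.416 against -0.0502 and 0.0181 in replicates 2 and 3.

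The 6 h difference was 198 rows within the numbers below 3000 and 0 within the higher numbers. Without single arrays it was 50, 2 and 39 (KO 0 h replicates 1, 2 and 3), 749, 13 and 14 (WT 0 h), 109 and 31 (KO 6 h replicates 2 and 3) and 441, 25 and 24 (WT 6 h), and 0 without the 2 WT arrays of lower numbers at 0 h. Fbxo32 and Il22ra1 were the 2 of 32 passing genes examined that passed whichever single array was left out.

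For the 24 h response no gene differed in limma (0 rows; 2165 had an unadjusted p under 0.05; smallest adjusted p 0.102). Mcm2, Slc25a10 and Krt16 had the smallest p among higher values, at 1.15 (adjusted p = 0.102), 0.82 (adjusted p = 0.102) and 3.52 (adjusted p = 0.195), and Cd59a, Fbxo32 and Hs3st6 among lower ones, at -1.17 (adjusted p = 0.102), -1.23 (adjusted p = 0.102) and -1.11 (adjusted p = 0.194). Krt6b differed by 3.72 (adjusted p = 0.314), Ptgs2 by 2.16 (adjusted p = 0.203) and S100a9 by 0.83 (adjusted p = 0.231). Camera called 9 lists. Cell cycle (median 0.20, adjusted p = 1.8e-05), Langerhans cell (0.33, adjusted p = 1.8e-05), wound keratin (0.29, adjusted p = 0.000161), wound repair (0.25, adjusted p = 0.000452), NRF2 (0.15, adjusted p = 0.0402), protease (0.03, adjusted p = 0.0402), cytokine (0.09, adjusted p = 0.0402), and neutrophil and monocyte genes (0.09, adjusted p = 0.0402) lay higher. Hair follicle genes lay lower (-0.13, adjusted p = 0.00353). There WT replicate 2 at 24 h stood apart, with a list mean of 0.586 against 0.104 and 0.0502 in replicates 1 and 3. With an estimated correlation each of the 9 had an adjusted p = 0.552, and adjusted over the list alone 6, 3, 5, 4, 1, 4, 0, 0 and 0 members passed in that order, against 0 over all genes. The count of rows was 32 without WT 0 h replicate 1, 2 without KO 24 h replicate 2 and 1 without KO 24 h replicate 3.

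Across the 22180 genes, the 6 h changes in WT and KO, which share no arrays, correlated with Pearson's r = -0.03 and Spearman's rho = 0.01, and the 24 h changes with r = 0.51 and rho = 0.41. These are correlations over genes, which are not independent replicates. Genes that rose in KO at 24 h had the same direction in WT in 552 of 727 rows, and genes that fell in 1386 of 1522, with median changes in WT of 0.10 and -0.25 against 0.50 and -0.58 in KO. At 6 h the same direction was seen in 128 of 370 and 310 of 802. Over all genes the direction was the same in 64.1% at 24 h and 51.3% at 6 h. These rows were chosen because they passed in KO, which favours large KO changes. Smaller WT medians are thus to be expected even if the genotypes responded equally. Within the numbers below 3000 the 6 h correlation was -0.41 and within the higher numbers 0.46, and it was 0.49 without the 4 WT arrays of lower numbers; within the higher numbers the 24 h correlation was 0.66. Between times, 8 rows passed in KO against WT at both 0 h and 6 h, against 0.502 for independent lists. Both comparisons share the estimate of each row's spread, so the lists are not independent. Cd3e, Il2rb, Klrb1b, Prf1, Trat1 and Trgv5 had the same sign, and the others, Fbxo32 among them, had opposite signs.

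**Figure D5:**
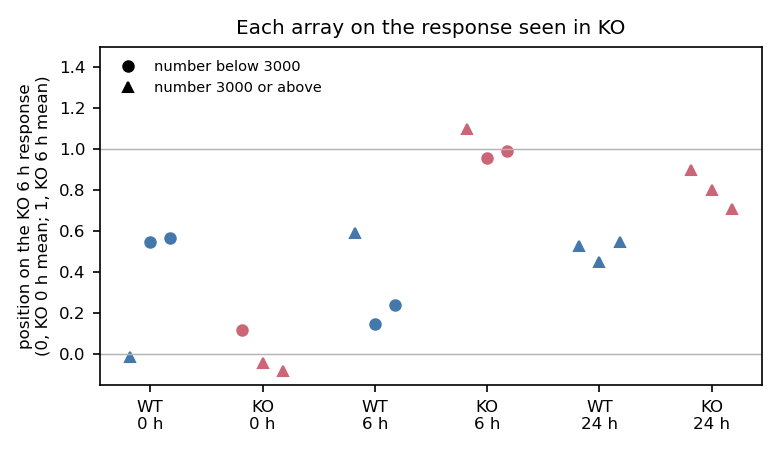
Position of each array (y axis) along the change from 0 h (0) to 6 h (1) in KO, for WT (blue) and KO (red) arrays, with circles for arrays of numbers below 3000 and triangles for the rest. WT replicates 2 and 3 lie at 0.55 and 0.57 at 0 h and at 0.15 and 0.24 at 6 h, while replicate 1 lies at -0.02 and 0.59.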

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

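The tests of explanations in this part were chosen after the results were seen, as were the contrast averaged over the times and the second scale of the clock gene test, which was added after the first scale had been read; the splits of the arrays were planned.

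The 6 h response differed between genotypes in 172 rows, by the test of the difference itself. Higher in the KO response were Gsta4 by 3.52 log2, Krt16 by 3.50, Rab31 by 2.28, Gadl1 by 2.08, Nrg1 by 1.90, Capn2 by 1.78, Aqp3 by 1.71, Ddr2 by 1.65, Mfge8 by 1.53, Crispld2 by 1.38, Mcm5 by 1.30, Utp4 by 1.29, Mcm2 by 1.13, Mcm3 by 1.07 and Mcm6 by 0.76. Lower were Fbxo32 at -1.89, Rspo3 at -1.83, Sostdc1 at -1.51, Slitrk6 at -1.46, Fam180a at -1.41, Hs3st6 at -1.37, Slc6a4 at -1.32, Rasgrp1 at -1.31, Kcnj2 at -1.28, Klhl24 at -1.26, Mrgprb3 at -1.25, Il22ra1 at -1.23, Cldn8 at -1.06, Egr1 at -0.91, Calml3 at -0.73, Acer1 at -0.72 and Dgat2 at -0.70. Camera also set the genotypes apart at 6 h for the lists of immediate early (median -0.357), junction (-0.142), lipid synthesis (-0.14), wound keratin (0.203), wound repair (0.211) and Langerhans cell genes (0.381). At 24 h it did so for Langerhans cell (0.327), wound keratin (0.29), wound repair (0.246), cell cycle (0.203), NRF2 (0.152), neutrophil and monocyte (0.093), cytokine (0.0858), protease (0.0303) and hair follicle genes (-0.126). None of these list calls held with an estimated correlation, where the smallest adjusted p was 0.703 at 6 h and 0.552 at 24 h.

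The 10272 rows that name no single gene were left out of the reported comparisons. When they were tested too, 7 of them passed between KO and WT at 0 h, 42 at 6 h and 7 at 24 h. Their differences reached 3.45, 3.16 and 3.25 log2 in size.

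The WT arrays of 0 h and 6 h were out of order along the KO response: replicates 2 and 3 lay at 0.55 and 0.57 of the way at 0 h and at 0.15 and 0.24 at 6 h, nearer the other time in 4 of 4 cases, while replicate 1 lay at -0.02 and 0.59. A single shift tied to the number below 3000 at every time is argued against as the whole source, because the difference between number classes correlated at -0.25 across rows between WT 0 h and WT 6 h (-0.194 at most with 1 array left out), but the other 5 pairs of groups at 0 h and 6 h correlated at 0.0344 to 0.458, so such a shift beside another source stays open. A shift of its own at 0 h may contribute, since that difference correlated at 0.458 between KO and WT at 0 h, against at most 0.331 for the other of 9 ways to set 1 array against 2, but so few ways decide nothing. An exchange of arrays between WT 0 h and WT 6 h stays open too: by 17 clock genes 1 of the 4 arrays lay nearer the other time, on a scale where arrays of 1 group at 24 h spread over up to 0.91, and a second scale from the KO arrays of lower numbers, where 4 of the 4 lay nearer the other time, was set aside, since it rests on 1 array at 0 h and placed the other KO arrays of 0 h at 0.58 and 1. A genotype difference in the time course stays open as well, and no array was moved to another group.

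T cell markers lay lower in KO at 0, 6 and 24 h by camera, without a call when the correlation was estimated (adjusted p of 0.261, 0.45 and 0.301), and Trgv5 lay lower in all 9 KO than in all 9 WT arrays. A loss of every minor cell type alike is argued against at 6 and 24 h. There the T cell list mean was -0.52 and -0.567 log2 (SE 0.139 each) in KO minus WT, and the Langerhans cell list mean 0.0426 and 0.0484 (SE 0.12 each). The T cell mean lay below the Langerhans cell mean by -0.335, -0.563 and -0.616 (SE 0.0862 each) at 0, 6 and 24 h. Averaged over the times it did so by -0.505 (SE 0.0498). At 0 h both lists were lower, at -0.69 (SE 0.139) and -0.355 (SE 0.12). List means also depend on how far members rise above background, which could not be assessed. The unequal falls at 0 h therefore do not show an unequal loss of cells. Strain variants around Ahr acting on the genes beside it are argued against too, with 0 of 18 measured T cell markers within 20 Mb of Ahr, which leaves variants acting at a distance untested. Fewer epidermal T cells, or less of these transcripts per cell, may each underlie it, and centred values of whole sheets, which carry no level of any transcript, cannot separate them; 2 of the 18 markers are each shared with another list.

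At 24 h many rows passed in KO and few in WT, although 0 rows passed limma's test of the difference (2165 at an unadjusted p under 0.05). A trend with gene span is argued against as the whole source: of the 2249 KO rows 1883 were still called once the trend was removed (1997 in all). The change at 24 h also followed the span as closely in WT (Spearman's rho -0.247) as in KO (-0.245). The span is the length of the gene in the genome, not of its transcript, so RNA quality itself was not tested. The start level of WT may contribute, because over the KO rows the slope of the WT on the KO change was 0.344 with all WT arrays of 0 h and 0.568 with the array of the higher number alone, a single array. Both slopes are lowered by the choice of rows that passed in KO, so neither measures how much smaller the WT response was. A smaller WT response remains open beside the start level.

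Other splits of the same arrays were counted for each count of rows. With 10 splits of 6 arrays the share is never under 0.1, which is too few. For KO against WT the real counts were 23, 513 and 4 at 0, 6 and 24 h and the highest others 231, 1 and 0 (2, 1 and 1 splits reached the real count). The split of 231 rows at 0 h sets the numbers below 3000 against the rest, and a split that calls so many more rows points to a structure of the samples. With the number as a block 20 rows passed by genotype. That block takes the same shift at every time, so it cannot remove a shift particular to 0 h. The 20 rows therefore do not show that the genotype calls are free of this structure. For the times against 0 h, the real counts were 0 and 7 in WT at 6 and 24 h and 1172 and 2249 in KO, and the highest others 53, 0, 1 and 0 (10, 1, 1 and 1 splits). Over 100 splits by genotype within times, 1 split reached the real count for the 6 h difference (172 rows, highest other 18). The same held for KO against WT averaged over the times (88 rows, highest other 4), a contrast chosen after the data were seen. All 100 splits reached it for the 24 h difference (0 rows, highest other 70). The other splits mix the genotypes, so genotype differences in single genes widen their spread and can lower their counts. These shares alone therefore do not exclude chance, and the 6 h count fell to 2 without KO 0 h replicate 2.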

How the results depend on the processing

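The fits without the WT arrays of lower numbers, the filter on a row's SD, the removal of the gene span trend, the mean over a gene's rows and the contrast of KO against WT averaged over the times were chosen after seeing the data; the other alternatives were planned, and the planned filter on mean signal was not run. Counts are of rows past an adjusted p of 0.05 in limma, and where no construction below gives the cause, the cause was not tested. Signal over background, lost by the centring, cannot show which calls rest on dim rows.

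Counts more than 1.5 times away from the reported ones were as follows. For KO against WT at 0 h (23 rows), quantile normalisation gave 15, trend and robust options 12, array weights 188, the SD filter (fewer rows tested) 47, the 6 arrays alone (fewer arrays) 0 and leaving out 1 array 5 to 59. For KO against WT at 6 h (513), they were 287 with quantile normalisation, 1025 with array weights, 192 with a 1.5-fold minimum, 0 with the 6 arrays alone and 16 to 1068 without 1 array. For KO against WT at 24 h (4), they were 12 over all rows, 23 with the SD filter, 1 with trend and robust options, 1 with the 6 arrays alone, 9 with the number as a block and 1 to 6 without 1 array. The WT change at 6 h (0) stayed at 0 without any 1 array. The KO change at 6 h (1172) gave 1856 with array weights, 661 with the 6 arrays alone, 515 at 1.5-fold and 159 to 1326 without 1 array. The WT change at 24 h (7) gave 264 with quantile normalisation, 3 with a median shift, 4 over all rows, 175 with the SD filter, 2 with trend and robust options, 164 with array weights, 2 with the 6 arrays alone, 14 without the span trend and 0 without any 1 array. The KO change at 24 h (2249) gave 1006 at 1.5-fold and 1029 to 1848 without 1 array.

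The 6 h difference (172) gave 79 over all rows, 429 with the SD filter, 47 with trend and robust options, 864 with array weights, 72 with the arrays of its 4 groups alone and 2 to 749 without 1 array. The 24 h difference (0; 2165 rows at an unadjusted p under 0.05 in limma) gave 3 with quantile normalisation, 30 with the SD filter, 9 with array weights and 0 to 32 without 1 array. KO against WT averaged over the times (88) gave 226 with array weights, 138 with the SD filter, 22 at 1.5-fold and 44 to 322 without 1 array. Lowest counts came without KO 0 h replicate 2 (KO 6 h, 6 h difference), KO 0 h replicate 2 or 3 (KO against WT at 0 h), KO 0 h replicate 3 (KO 24 h), WT 6 h replicate 3 (KO against WT at 6 h) and WT 6 h replicate 2 (average). Highest counts came without WT 0 h replicate 1 (0 h and both differences), WT 6 h replicate 1 (KO against WT at 6 h, average), KO 6 h replicate 1 (KO 6 h), KO 24 h replicate 2 (KO against WT at 24 h) and KO 0 h replicate 1 (KO 24 h).

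Without the 2 WT arrays of lower numbers at 0 h, counts were 0 for KO against WT at 0 h, 15 and 114 for WT at 6 and 24 h and 0 for the 6 h difference. Without those at 6 h they were 1 for KO against WT at 6 h, 2 for WT at 6 h, 2 for the 6 h difference and 20 for the average. Without all 4 they were 1 and 0 for KO against WT at 0 and 6 h, 44 and 423 for WT at 6 and 24 h, 0 and 1 for the differences at 6 and 24 h and 13 for the average; a lone WT array is assumed there to vary like the other groups. Without the 4 arrays 5 list calls turned direction: cornified envelope at 0 h (adjusted p = 0.778, from 0.0219 to 0.778 over its alternatives), immediate early genes in WT at 6 h (0.213; from 0.000304 to 0.556), cell cycle (0.293; from 0.0347 to 0.775) and T cell markers (0.954; from 0.0289 to 0.954) in WT at 24 h, and junctions in the 6 h difference (0.849; from 0.0221 to 0.849). Correlations of the WT and KO responses (-0.03 at 6 h, 0.51 at 24 h) became 0.486 and 0.635 without the 4 arrays and -0.385 and 0.703 among genes past the threshold in either genotype.

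Replicate numbers are shared between groups and were not taken to pair the arrays: of 45 pairs of equal number 9 correlated over 0.1 and 10 under -0.1 (from -0.458 to 0.251). In 1 pair of groups, WT at 6 h and KO at 24 h, which no comparison sets side by side, all 3 correlations were over 0.1 (0.131, 0.136 and 0.142). With the replicate number as a block, counts were 8 and 314 for KO against WT at 0 and 6 h, 0 for WT at 24 h and 49 for the 6 h difference, and within 1.5 times of the reported count for the other comparisons.

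Over the named genes, 3314 of 4673 values of passing genes under an alternative stayed past the threshold and 1359 did not, with 0 turned in direction; of values that had not passed, 70 came past it. Of the list results, 67 lost a call with an estimated correlation, 54 with fry, 3 with all rows of the members, 2 with the mean over rows and 23 without the 4 arrays, the 5 that turned direction included. A call was gained by 7 with fry, 2 with all rows of the members, 1 with the mean over rows and 21 without the 4 arrays.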

Other observations

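The contrast in the next paragraph was chosen after the data were seen, as were the checks of gene span and of genes near Ahr; the tests of gene lists were planned.

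Averaged over the 3 times, 88 rows differed between KO and WT, 12 higher and 76 lower, with 2884 at an unadjusted p under 0.05. Trgv5 was lower in KO by -2.94 log2 (SE 0.17, adjusted p = 7.56e-07), Cd7 by -1.71 (SE 0.18), Cd3e by -1.43 (SE 0.132, adjusted p = 0.000118), Cd3g by -1.40 and Il2rb by -0.60. Of 18 T cell markers 6 passed, all lower (12 adjusted over the list alone), with a camera adjusted p = 6.82e-14 and an adjusted p = 0.0767 with an estimated correlation. Outside that list, Trat1 was at -1.001, Klrb1b at -0.85, Ctla2a at -0.80, Rgs1 at -0.78, Prf1 at -0.73, Dpep2 at -0.72, Mfge8 at -1.11 and Adh7, a retinol-oxidising dehydrogenase, at -0.87 (adjusted p = 0.000386). Ahr itself was at -0.71 (SE 0.0827, adjusted p = 0.000939). Higher in KO were Il1b by 1.24 (SE 0.232, adjusted p = 0.0299), Gsdmc by 1.16, Nop56 by 0.61, Samhd1 by 0.58, Ube2l6 by 0.40, Cd59a by 0.39, Zbp1, a sensor of nucleic acids, by 0.39, Il3ra by 0.33, the T cell co-receptor gene Cd8a by 0.31 and Thoc3 by 0.30. The smaller passing differences included Egr3 at -0.39, Lamb3 at -0.39, Krt1 at -0.37, Smpd1 at -0.31 and Evpl at -0.30.

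By camera, AhR target genes were lower in KO averaged over the times (median -0.16; 10 of 12 below 0, adjusted p = 0.00619), and with an estimated correlation the adjusted p was 0.0767. Fry called 6 lists in this contrast, AhR targets and T cell markers (adjusted p = 0.00065 for both), junction (0.00708), immediate early (0.0322), interferon (0.0322) and lipid synthesis genes (0.047). None of the 12 AhR targets passed (0 adjusted over the list alone), with Cyp1b1 at -0.27 (adjusted p = 0.239), Nqo1 at -0.24 (adjusted p = 0.245), Aldh3a1 at -0.24 (adjusted p = 0.303) and Cyp1a1 at -0.20 (adjusted p = 0.304). Lipid synthesis (median -0.14, adjusted p = 1.91e-06), junction (-0.11, adjusted p = 1.91e-06), immediate early (-0.16, adjusted p = 4.9e-07), basal keratinocyte (-0.08, adjusted p = 0.0038) and sebaceous gland genes (-0.10, adjusted p = 0.0306) lay lower, and wound keratins (0.12, adjusted p = 2.31e-06) and interferon genes (0.07, adjusted p = 0.00135) higher. With an estimated correlation their adjusted p were 0.179, 0.0767, 0.172, 0.179, 0.603, 0.179 and 0.0996, and 1, 1, 1, 0, 0, 0 and 1 members passed (3, 9, 5, 3, 2, 8 and 1 adjusted over the list alone). The count of 88 was 55 without KO 0 h replicate 2, 289 without KO 6 h replicate 1, 55 without KO 6 h replicate 3, 322, 44 and 49 without WT 6 h replicates 1, 2 and 3, and 50, 58 and 133 without KO 24 h replicates 1, 2 and 3. It was 20 without the WT arrays of lower numbers at 6 h and 13 without all 4. Of 29 passing genes examined, Adh7, Ahr, Cd3e, Dpep2, Il2rb, Mfge8, Prf1, Rgs1, Trat1 and Trgv5 passed under every alternative.

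Camera called 7 lists in none of the 9 planned comparisons. Their smallest camera adjusted p were 0.0666 for AhR targets (KO against WT at 0 h), 0.0645 for cholesterol synthesis and 0.0658 for endothelial markers (KO at 24 h), 0.105 for hypoxia and glycolysis (WT at 6 h), 0.153 for adipocyte (KO at 24 h), 0.22 for mast cell (KO against WT at 6 h) and 0.245 for dermal fibroblast markers (KO at 6 h). Fry did call AhR targets lower in KO at 0 h and 6 h (adjusted p = 0.0132 and 0.00707) and endothelial and adipocyte markers higher in KO at 24 h (adjusted p = 0.0341 for both).

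Changes correlated across rows with the span of the gene, with Spearman's rho of -0.245 in KO and -0.247 in WT at 24 h and -0.183 in KO at 6 h. Rows that fell in KO at 24 h had a median span of 50.2 kb and those that rose 9.87 kb, against 16.4 kb over all rows; 99.2% of rows had a span. Of 164 rows within 20 Mb of Ahr, 2 passed between KO and WT at 6 h (Ahr and Sostdc1; 1.22%, against 2.18% of all rows) and 0 at 0 h and 24 h (against 0.0978% and 0.017%). The median size of the KO minus WT difference was 0.0962, 0.11 and 0.0822 log2 in these rows at 0, 6 and 24 h, against 0.067, 0.0845 and 0.0679 over all rows. In KO, 8.54% of them passed at 6 h and 17.1% at 24 h against 0 h, compared with 4.98% and 9.56% of all rows. In the 6 h difference between genotypes 1.83% passed, against 0.731%. None of these shares was tested against the share over all rows.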
